A study of Mus musculus with 4 samples.

How the data were processed

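RNA from the neural retina of mice was measured by RNA-seq in 4 samples, which the sample titles name lanes 1 to 4. Per the labels' protocols, each sample came from neural retina pooled from 5 mice of both sexes aged 2 months, and each library used 5 ug of total RNA with an insert of 350 bp, give or take 25 bp. The growth protocol names C57BL/6J mice, whereas the strain label also names 129SvEvTac, and both are left as the labels give them. Nothing in the labels says that the lanes came from separate pools of mice, so the spread between them may be technical. The track names in the deposited coverage files carry the word prpf8_wt with the numbers 1 to 4, which the sample labels do not use.

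Each sample had a coverage signal of unique alignments and a coverage signal of non-unique alignments, as the authors deposited them. Per the file headers these are bedGraph tracks of unique and of non-unique mappers, and every deposited signal value is a whole-number depth over an interval that was not scaled to library size. The genome build is mm9, per the submitters' processing notes. The aligner, its version and the read filters are not given in the sources used here. In lane 1 the highest non-unique depth was 15425 on chromosome 4, 15404 on chromosome 7, 15412 on chromosome 15 and 15419 on chromosome X, and it was 30771 on the mitochondrial chromosome and 30779 on chromosome 1, so that non-unique alignments appear to be counted at each location and their base totals then exceed the bases sequenced.

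Gene names came from GENCODE release M21, which is not on the files' build, and no coordinates were converted. A gene model was used only where its own pattern of exon and intron lengths was found to the base in the edges of the unique coverage on the same chromosome, within 10000000 bp of the model's position, with at least 4 splice boundaries and 60% of the boundaries matched and a unique best position. An edge was a change of depth by a factor of 3 or more to or from a depth of at least 4, in the summed lanes. Of 32093 gene models, 23981 had 3 or more exons and 11509 were placed, with a median of 16 boundaries matched. Mirrored models, which should not match, were placed 52 times, or 0.452% of the number placed, and 99.5% of the placed models shared their shift with a neighbour. After 202 models that overlapped another by 50% or more were dropped, 11307 genes were measured. Genes with fewer than 3 exons, genes with low coverage and genes with near-identical copies were mostly not placed and count as not measured. Placement needs coverage, so lists of rare cell types hold only their detected members. Coordinates are those of the match on the files' own build, 1-based. Strand was not used, and 629 genes shared over 10% of their exonic bases with another placed gene, so their values can include reads of that gene. Mitochondrial genes were not named, and the mitochondrial chromosome was taken as a whole.

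The level of a gene, called normalised coverage, was its mean unique depth over exonic bases for each 1000000000 uniquely aligned bases of the lane, and a pseudocount of 1 was added before taking log2. Read equivalents were aligned bases divided by 120 bp, the most frequent length of isolated covered blocks. Lanes were compared by a chi-square test per gene of read equivalents against the lanes' shares of the total, divided by the median dispersion, with Benjamini-Hochberg adjustment over genes with 50 or more read equivalents and a threshold of 0.05. The expected share of lane 4 in this test corresponds to a log2 ratio of -0.10 between lane 4 and lanes 1 to 3, because measured genes took a smaller part of its bases, and higher or lower by the lane test means above or below that share. Gene lists were fixed before the data were examined, and the median log2 level of each list was set against 10000 random lists of the same size in a two-sided gene permutation test, with Benjamini-Hochberg adjustment over 20 lists. The test permutes genes and not samples, so its p-values describe these libraries, and genes that vary together make them too small. Rod to cone gene pairs were tested with an exact two-sided sign-flip permutation test over pairs.

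Lanes 1 to 3 were counted as 1 sample, because their differences did not grow with depth as those with lane 4 did. For each pair of lanes the dispersion of the highest eighth of genes by read equivalents was divided by that of the lowest eighth, and pairs under 1.5 were joined. This limit was set after the data were examined, and the designed analysis had counted each lane. Means and SDs are therefore over n = 2, the mean of lanes 1 to 3 and lane 4. Such an SD leaves out the spread among lanes 1 to 3 and can be far smaller than it, so a small SD does not show precision. Rgr, for example, had an SD of 0.000925, with levels of 1.57, 1.68 and 1.66 in lanes 1 to 3 and 1.64 in lane 4. With 2 samples, or with 4 lanes, an exact sign-flip test cannot reach 0.05.

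The named genes were fixed by rule before the data were examined. They were the 25 genes with the highest level, the 3 highest members and the lowest member of each list, the 15 genes with the highest non-unique share at a mean total depth of 10 or more, up to 5 genes with the smallest adjusted p between lanes, both members of each rod to cone pair, the 10 low inclusion exons whose genes had the highest median internal exon depth, and the sex chromosome genes. Mip, Crygc and Lim2 of the lens list are named outside this rule, and other genes outside it are said to be so where they appear. A few genes that the rule selects, and 2 of the planned gene pairs, are not reported here.

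Placement and the lane test were tested on simulated data. Of 1000 planted gene models 968 were placed, 966 of them at the planted position, and 1 of 1000 mirrored models was placed. In read equivalents simulated for 11259 genes, the lane test called 69 of 100 genes changed 1.5-fold in lane 4, 96 of 100 changed 2-fold and 11 of 11107 unchanged genes. The simulated counts had the same dispersion for all genes, whereas the real dispersion with lane 4 rose with coverage. The planted gene models had most of their boundaries visible whatever the expression of the gene. These rates therefore need not hold for the real lanes. Alternatives covered leaving out each lane, adding non-unique coverage, another pseudocount, scaling without the mitochondrial chromosome, median depth, filters on low depth, and other thresholds for each count. The alternatives for the comparison of lane 4 by gene list, for levels of named genes, for the dispersion of lanes 1 to 3, for leaving out genes with shared bases and for counting each lane as a sample were added after the data were examined. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.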

Results

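Poly-exonic transcripts of the mouse neural retina were measured in 4 RNA-seq lanes of a single group, retina from mice aged 2 months. The study's title concerns the comparison of RNA-seq alignment algorithms, and the labels give no second group, so the comparisons are between unique and non-unique coverage, between lanes and between genes. Lanes 1 to 4 held 4.09, 4.11, 3.88 and 3.83 gigabases of unique alignments, which correspond to 34.1, 34.2, 32.3 and 31.9 M read equivalents. Unique alignments covered 282, 282, 275 and 313 megabases of the genome. The 11307 measured genes took 65.5%, 65.5% and 65.6% of the uniquely aligned bases in lanes 1 to 3 and 61.1% in lane 4. The mitochondrial chromosome took 1.88%, 1.90%, 1.88% and 1.78%.

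Non-unique alignments made up 36.0% ± 2.22 of all aligned bases (SD, n = 2), with 34.6%, 34.4% and 34.3% in lanes 1 to 3 and 37.6% in lane 4. The share differed between chromosomes by more than that spread. It was 88.2% ± 1.02 on chromosome Y and 52.5% ± 1.91 on chromosome X, against 23.6% ± 1.39 on chromosome 11 and 25.6% ± 3.17 on chromosome 9. The mitochondrial chromosome stood at 35.7% ± 1.41. Unique bases exceeded non-unique bases in all 4 lanes, the most extreme outcome of an exact sign-flip test, which cannot reach 0.05 with 4 lanes.

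Over all genes, levels were closer among lanes 1 to 3 than between them and lane 4. Across genes, which are not independent replicates, Pearson's r of the log2 levels was 0.998 for each pair among lanes 1 to 3 and 0.991 to 0.992 for pairs with lane 4, with a median of 0.995 over the 6 pairs. The median absolute log2 difference was 0.05 within lanes 1 to 3 and 0.13 for pairs with lane 4. Dispersion of the read equivalents was 1.67 to 1.70 within lanes 1 to 3 and 7.32 to 7.70 for pairs with lane 4. From weakly to strongly covered genes it changed by a factor of 0.945 to 1.09 within lanes 1 to 3 and of 16.2 to 16.3 with lane 4. In lanes 1 to 3 alone the chi-square test with Benjamini-Hochberg adjustment called 0 of 11216 genes, with 564 at an unadjusted p under 0.05. Without division by their own dispersion of 1.66 it called 138, against 4900 to 5007 when lane 4 replaced any of these lanes. Lanes 1 to 3 therefore differed by no more than evenly overdispersed sampling noise and were counted as 1 sample.

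Among the genes with the smallest adjusted p between lanes, a ranking that favours strongly covered genes, were Gnat1, the rod transducin alpha subunit, Cryaa, a lens chaperone crystallin, Gnb1, a G protein beta subunit, and Guca1b, a guanylate cyclase activator. Cryaa had a level of 293 in lanes 1 to 3 and 27.7 in lane 4, Gnat1 5740 and 3853, and Guca1b 816 and 493. Over all 4 lanes, 1220 of 11260 genes (10.8%) passed the chi-square test with Benjamini-Hochberg adjustment, 825 of them above and 395 below the share that the test expects for lane 4. The dispersion that divided this test, 3.57, includes the difference of lane 4 itself, and the count was 3066 with the dispersion of lanes 1 to 3 (1894 above and 1172 below, a choice made after the data were examined) and 5178 for genes that differ between lanes without division. The adjusted p was 4.7e-284 for Gnb1 and 3.1e-252 for Guca1b, and it was too small to be represented for Gnat1 and Cryaa. The test compares the reads of these lanes and not conditions, and without lane 4 it called 0 genes.

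Genes of rod phototransduction were among the most strongly covered genes. Gnat1 had a normalised coverage of 4796 ± 1334 (SD, n = 2, as for all levels that follow) at chromosome 9, 107576805 to 107582043. Gnb1 stood at 1566 ± 306, Pdc (phosducin, a regulator of G protein beta and gamma subunits) at 1269 ± 221 and Sag (rod arrestin, which ends the light response) at 1252 ± 270. Other photoreceptor genes among the 25 highest were Prph2 (989 ± 136) and Rom1 (588 ± 61.0), tetraspanins of the outer segment disc rim, Pde6g (776 ± 113) and Pde6b (671 ± 92.0), subunits of the rod phosphodiesterase, Guca1b (655 ± 228) and Guca1a (499 ± 94.4), activators of guanylate cyclase, Rbp3 (651 ± 99.9), the retinoid carrier of the matrix between photoreceptors and pigment epithelium, Unc119 (566 ± 129) and Tulp1 (526 ± 76.7), which serve protein transport in photoreceptors, and Nrl (517 ± 116), the transcription factor of rod fate. Also among the 25 were Aldoa (1027 ± 217) and Pkm (855 ± 131), glycolytic enzymes, Glul (771 ± 10.8), glutamine synthetase of Müller glia, Atp1b2 (494 ± 12.7), a subunit of the sodium pump, Eef1a1 (639 ± 70.4), a translation elongation factor, Snap25 (581 ± 29.3), Slc17a7 (543 ± 89.7) and Syp (529 ± 60.2), proteins of transmitter release, and Hnrnpa2b1 (499 ± 1.67), an RNA-binding protein. The 25 genes with the highest totals of aligned bases took 12.7% ± 1.29 of exonic unique bases, 13.6% in each of lanes 1 to 3 and 11.7% in lane 4.

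The rod list had a median level of 517 over 17 measured genes, against 7.50 for all genes, and the list of genes shared by rods and cones had a median of 191 over 22 genes. The cone list stood lower, at 47.0 over 13 genes, led by Gnb3 (147 ± 11.5), a G protein beta subunit, Arr3 (145 ± 10.6), cone arrestin, and Gngt2 (141 ± 1.22), a cone transducin gamma subunit. The lowest members were Esrrb (70.0 ± 9.20), a nuclear receptor, in the rod list, Cngb3 (3.52 ± 0.204), a cone channel subunit, in the cone list, and Rpgr (9.39 ± 1.14), a ciliary protein, in the shared list. Each of the 3 lists lay above random lists in the gene permutation test with p = 0.0002, the smallest that 10000 random lists can give (adjusted p = 0.0005). By the lane test, 13 of the 17 rod genes were lower in lane 4 and 0 were higher (14 called when adjusted over the list alone). Of the 22 shared genes 8 were lower and 5 were higher (15 over the list alone), and of the 13 cone genes 2 were lower and 0 higher (3 over the list alone). The 5 higher genes, all but Rpgrip1 outside the rule for named genes, were Rp1 and Rpgrip1, proteins of the photoreceptor cilium, Impg2, a matrix proteoglycan, Gucy2f, a guanylate cyclase, and Otx2, a transcription factor. The lane test divides all genes by the same dispersion, whereas dispersion with lane 4 rose with coverage. Strongly covered genes are therefore called more readily, and the share called among genes of like coverage was not computed. As a list, rod genes in lane 4 over lanes 1 to 3 did not pass against level-matched random lists (gene permutation test, adjusted p = 0.0653). The rod median log2 ratio was -0.28, or -0.08 with the trend described below removed.

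Other retinal cell types were represented by strongly covered marker genes. The Müller glia list had a median of 38.3 over 12 genes, led by Glul, Dkk3 (208 ± 17.7), a secreted Wnt regulator, and Apoe (181 ± 22.7), an apolipoprotein, with Sox9 (2.80 ± 0.129), a glial transcription factor, lowest. The amacrine list had a median of 37.2 over 10 genes, led by Calb2 (112 ± 7.23), a calcium-binding protein, and Pax6 (96.8 ± 7.49), an eye transcription factor, while Th (0.832 ± 0.212), the dopamine synthesis enzyme, was lowest. The bipolar list had a median of 28.5 over 16 genes, led by Pcp2 (334 ± 9.99), a G protein modulator, and Cabp5 (66.9 ± 4.45), a calcium-binding protein, with Nyx (4.94 ± 0.180), a synaptic protein of ON bipolar cells, lowest. Pcp2 shared 37.3% of its exonic bases with another placed gene, so its level can include reads of that gene. These lists passed the gene permutation test at adjusted p = 0.0005, 0.0008 and 0.0005.

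The ganglion cell list had a median of 20.7 over 10 genes, led by the neurofilament genes Nefl (106 ± 8.26) and Nefm (66.9 ± 8.21) and by Sncg (55.5 ± 2.10), a synuclein, with Opn4 (1.09 ± 0.0766), melanopsin, lowest. It passed the gene permutation test at adjusted p = 0.0253, but with median depth the adjusted p was 0.0769 and with genes placed by 8 or more boundaries it was 0.886. The horizontal cell list had a median of 22.6 over 5 genes and did not pass the gene permutation test (adjusted p = 0.0936). Its highest members were Sept4 (69.4 ± 5.26), a septin, Ndrg1 (67.3 ± 3.56), a stress-response gene, and Prox1 (22.6 ± 0.213), a homeobox factor, and its lowest was Lhx1 (1.20 ± 0.0278), a LIM homeobox factor.

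Genes of the ribbon synapse, of glycolysis and of the cilium were also above random lists. The ribbon synapse list had a median of 84.2 over 17 genes, led by Snap25, Slc17a7 and Syp, with Bsn (10.8 ± 0.824), the scaffold protein bassoon, lowest. The glycolysis and creatine kinase list had a median of 111 over 18 genes, led by Aldoa, Pkm and Ldha (490 ± 109), lactate dehydrogenase, with Slc2a1 (40.2 ± 4.64), a glucose transporter, lowest. The photoreceptor cilium list had a median of 23.2 over 20 genes, led by Rpgrip1 (180 ± 11.5), Rp1l1 (85.6 ± 4.01) and Bbs7 (52.6 ± 4.91), with Nphp4 (3.61 ± 0.0750) lowest. Their adjusted p values in the gene permutation test were 0.0005, 0.0005 and 0.0008. In lane 4, 13 of the 18 glycolytic genes were lower and 0 higher by the lane test (13 adjusted over the list alone), and 8 of the 20 cilium genes were higher and 0 lower (9 adjusted over the list alone). Here too the lane test calls strongly covered genes more readily. After removal of a trend with GC content, length and level, described below, neither list passed against random lists (gene permutation test, adjusted p = 0.151 and 0.137). With level left out of that trend, glycolysis passed (gene permutation test, adjusted p = 0.0267) and cilium did not (0.060). The visual cycle list had a median of 11.96 over 11 genes and did not pass the gene permutation test (adjusted p = 0.272), from Rbp3, Abca4 (189 ± 16.3), a retinoid flippase, and Rdh12 (161 ± 13.5), a retinol dehydrogenase, down to Rpe65 (0.621 ± 0.0536), the isomerase of the pigment epithelium.

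**Figure D1:**
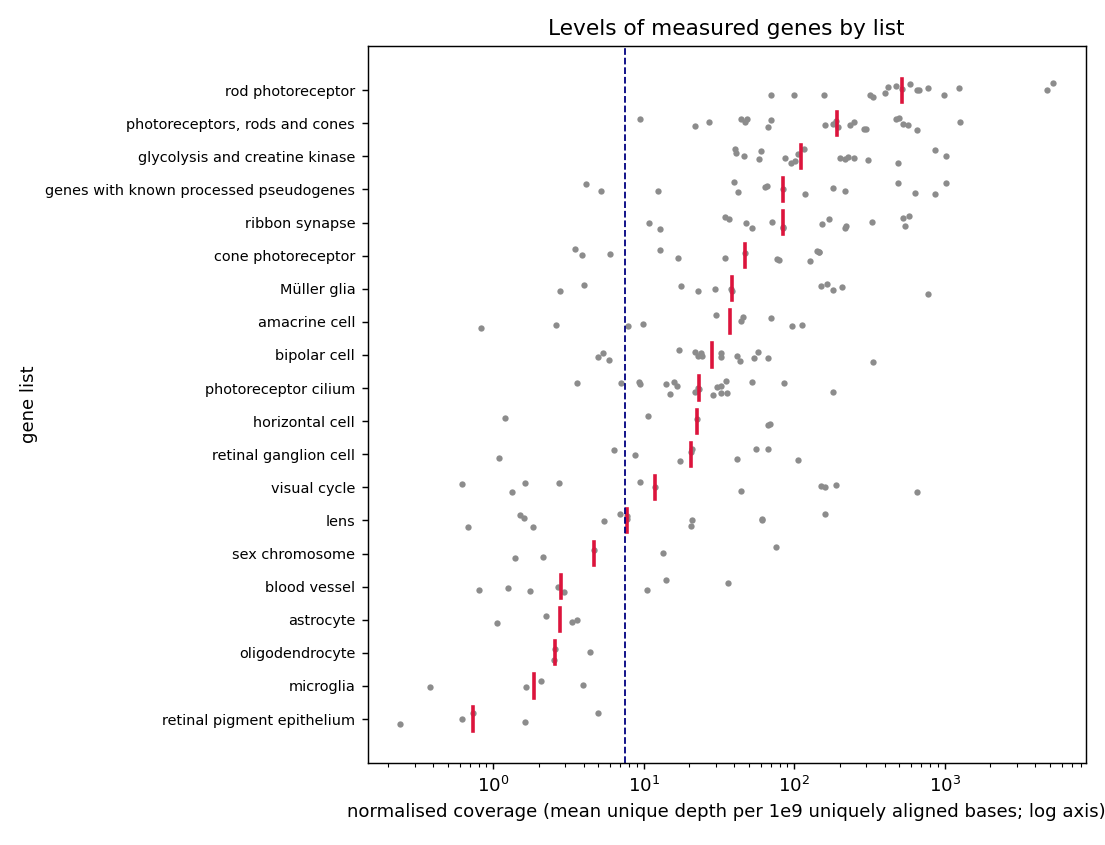
Normalised coverage of each measured gene, mean of 2 samples, on a log axis, by gene list; red bars mark list medians and the dashed line the median of all genes, 7.50. Medians run from 0.731 for the retinal pigment epithelium list to 517 for the rod list.

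Of the lists of other tissues and cell types, only that of the retinal pigment epithelium lay below random lists. The retinal pigment epithelium list had a median of 0.731 over 5 measured genes (gene permutation test, adjusted p = 0.00764). Ttr, a thyroxine carrier, stood at 4.98 ± 1.31, Rgr, an opsin, at 1.64 ± 0.000925, Dct, a melanin synthesis enzyme, at 0.731 ± 0.175 and Tyrp1, another such enzyme, at 0.242 ± 0.1002. Lists of blood vessel, microglia and astrocyte genes had medians of 2.82, 1.86 and 2.80, and neither they nor the oligodendrocyte list passed the gene permutation test (adjusted p = 0.0894, 0.0852, 0.199 and 0.249). In the vessel list Kdr (36.1 ± 0.0284), a VEGF receptor, Rgs5 (14.05 ± 2.30), a pericyte gene, and Flt1 (10.6 ± 0.409), another VEGF receptor, were highest and Vwf (0.8003 ± 0.0419), a clotting factor, lowest. Ctss (3.97 ± 0.0813), a protease, Csf1r (2.08 ± 0.164), a growth factor receptor, and C1qb (1.65 ± 0.229), a complement component, led the microglia list, in which Aif1 (0.381 ± 0.190) was lowest. Aldh1l1 (3.60 ± 0.482), Gfap (3.34 ± 0.243) and S100b (2.25 ± 0.530) led the astrocyte list and Pdgfra (1.06 ± 0.00584) was lowest. In the oligodendrocyte list Cnp, a phosphodiesterase of myelin, stood at 4.37 ± 0.235 and Mbp, a myelin protein, at 2.52 ± 0.0290. In the cornea list only Aldh3a1, a crystallin of the cornea, was measured, at 1.58 in lanes 1 to 3 and 0.00423 in lane 4. No gene of the red blood cell list was measured.

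Lens genes differed most between lanes. The lens list had a median level of 7.74 over 13 genes and did not differ from random lists (gene permutation test, adjusted p = 0.746). Without lane 4 its median lay 0.57 above that of all genes on the log2 scale, and with all lanes it lay below it (-0.16). Cryaa (161 ± 188), Crybb2 (60.9 ± 59.5) and Cryba1 (60.8 ± 52.6), crystallins of the lens, were highest and Bfsp1 (0.683 ± 0.0110), a filament protein of lens fibres, was lowest. By the lane test 10 of the 13 were lower in lane 4 and 1 was higher, or 12 in either direction when adjusted over the list alone. Crybb2 stood at 103 in lanes 1 to 3 and 18.8 in lane 4, and Mip, the water channel of lens fibres, at 10.3 and 0.598. Crygc, a gamma crystallin, went the other way, from 0.355 to 3.31.

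**Figure D2:**
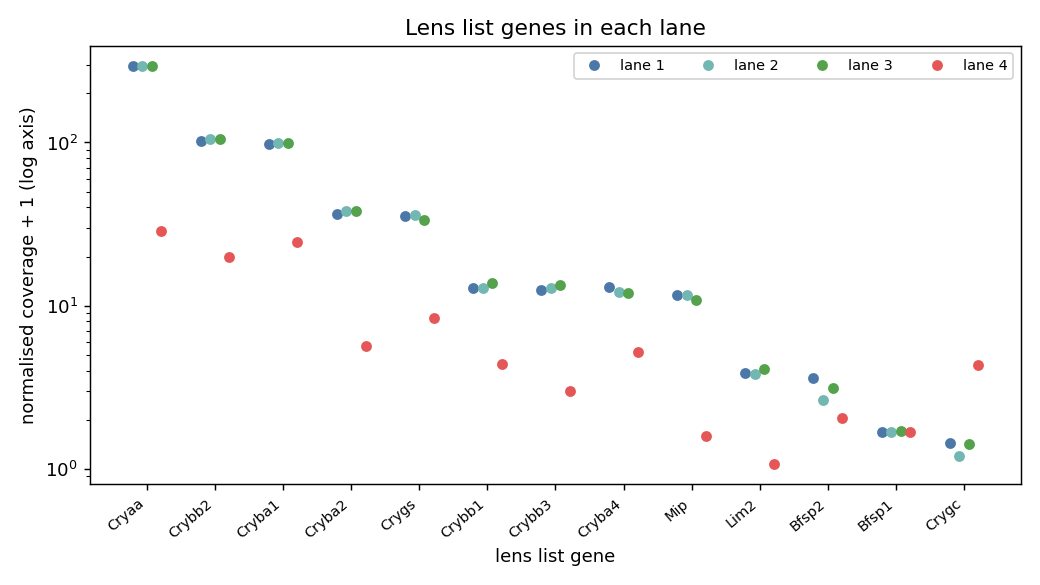
Normalised coverage plus 1 of the 13 measured lens list genes in each lane, on a log axis; each point is a lane. Lane 4 lies below lanes 1 to 3 for Cryaa (27.7 against 293) and above them for Crygc (3.31 against 0.355).

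The rod member was higher than its cone counterpart in 9 of 9 gene pairs. The mean log2 ratio was 4.17 ± 1.56 (SD over pairs), with an exact two-sided sign-flip permutation p of 0.00391, the smallest that 9 pairs allow. The cyclic nucleotide gated channel pair Cnga1/Cnga3 had a log2 ratio of 6.09 ± 0.11 (SD, n = 2, as for each pair), and the transducin pair Gnat1/Gnat2 5.92 ± 0.20. The phosphodiesterase pairs Pde6g/Pde6h, Pde6b/Pde6c and Pde6a/Pde6c stood at 5.44 ± 0.04, 4.24 ± 0.23 and 3.74 ± 0.19. Levels are mean depths over the chosen transcript, which had 900 exonic bp for Pde6g and 5940 for Pde6h. Their read equivalents over the 4 lanes were 97585 and 13892, so the ratio of this pair depends on the chosen transcripts. The second channel pair Cngb1/Cngb3 had 4.48 ± 0.14, the G protein pair Gnb1/Gnb3 3.39 ± 0.17 and the arrestin pair Sag/Arr3 3.08 ± 0.21. The transducin gamma pair Gngt1/Gngt2 was lowest at 1.16 ± 0.01. Ratios were of log2(level + 1), which understates the ratio where the cone gene was low, as for Cngb3 and Cnga3. For Cngb1, 26.1% of the coverage was non-unique, which its level leaves out. Whole neural retina was measured, and whether other cell types also express the paired genes was not tested, so the ratios need not compare rods with cones alone. The genes are not independent replicates, since Pde6c enters more than a single pair.

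**Figure D3:**
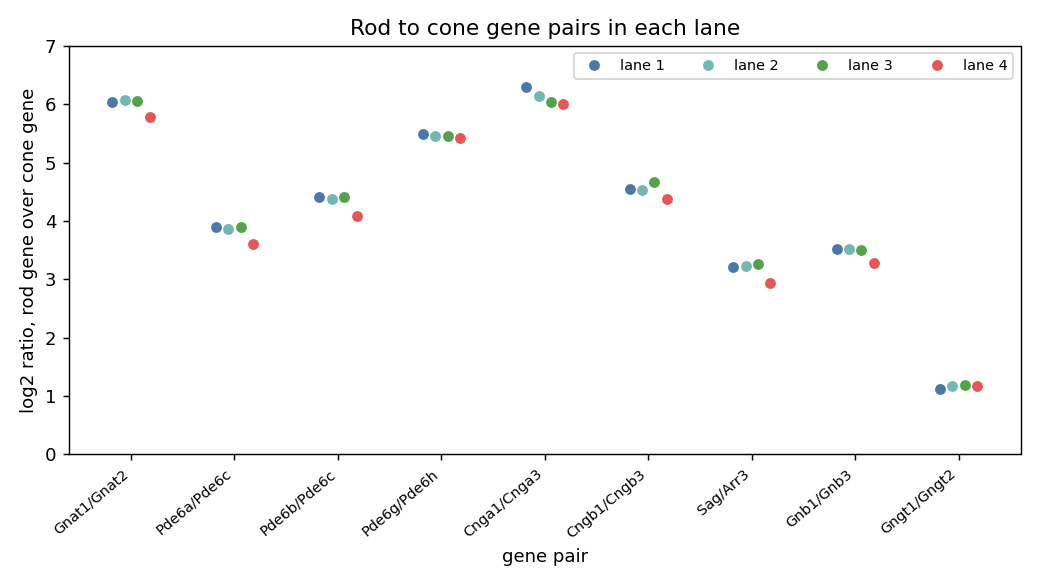
The log2 ratio of the rod gene over the cone gene for 9 pairs; each point is a lane. All points lie above 0, from 1.16 for Gngt1/Gngt2 to 6.09 for Cnga1/Cnga3 in the mean of 2 samples.

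Non-unique alignments dominated a small set of the measured genes. Placement used unique coverage, and genes with near-identical copies were mostly not placed, so the shares that follow do not describe all genes. Whether the genes named here have copies elsewhere in the genome was not tested. At least 50% of exonic aligned bases were non-unique in every lane for 154 of 11257 genes (1.37%), while 93.1% of genes had under 5% (mean over samples). Tpt1, a translationally controlled protein, had 97.7% ± 0.475 and a level of 4.13 from unique coverage, and Ppia, cyclophilin A, had 96.8% ± 0.586 and 5.24. Among the 15 genes with the highest share were also Tuba1c (97.5%), a tubulin, Sumo2 (93.4%), a ubiquitin-like modifier, the ribosomal protein genes Rps27 (96.7%), Rpl31 (94.4%) and Rpl19 (91.0%), the neighbouring splicing genes Mfap1b (96.3%) and Mfap1a (91.1%), Pigk (96.8%), which acts in GPI anchoring, the zinc finger gene Zfp781 (94.1%), the ribonuclease gene Rnaset2a (92.3%), and Fam177a (99.6%), Gm14305 (98.4%) and 9030025P20Rik (91.3%). Levels of these genes from unique coverage are uncertain, and Fam177a shared 98.5% of its exonic bases with another placed gene, while the placement of Gm14305 rests on its own pattern without a neighbour at the same shift. The list of genes with known processed pseudogenes had a median non-unique share of 28.2% over 15 genes, above random lists (gene permutation test, p = 0.0002, the smallest possible), and a median level of 84.3 (adjusted p = 0.0005), from Aldoa, Pkm and Eef1a1 down to Tpt1.

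Among the measured genes, the median coverage of introns was low and the median ratio between transcript ends was near even. Placement needed changes of depth by a factor of 3 or more at splice boundaries, which favours genes with low intron depth. Medians over genes do not show how even the coverage of single genes was. The median gene had an intron depth of 3.79% ± 0.566 of its exon depth over 10013 genes, with 3.38%, 3.41% and 3.37% in lanes 1 to 3 and 4.19% in lane 4. The depth in the last part of the transcript over that in the first, each 20% of the exonic length, was 1.05 ± 0.00569 over 9461 genes.

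Some internal exons of strongly covered genes had low coverage. Mean depth was under 20% of the gene's median internal exon in every lane for 479 of 68594 exons (0.698%), in 320 genes. Exon 2 of Hnrnpa2b1, 36 bp at chromosome 6, 51417390 to 51417425, had 2.62% ± 1.13 (SD, n = 2, as for each exon). Exon 2 of Hk1, the hexokinase of most tissues, 48 bp at chromosome 10, 61815806 to 61815853, had 0.0595% ± 0.0146, and its exon 10 had 2.88% ± 0.107. Exons 2 and 3 of Rtn4, the gene of the neurite growth inhibitor Nogo, had 3.21% ± 0.0332 and 13.4% ± 1.89, exon 3 being 2361 bp long at chromosome 11, 29606410 to 29608770. Exon 2 of Gnas, a stimulatory G protein gene, 2327 bp at chromosome 2, 174153609 to 174155935, had 2.41% ± 0.167. Exon 2 of Hnrnph1, a splicing regulator, had 13.1% ± 2.58, exons 2 and 3 of Agpat3, a lipid acyltransferase, 1.51% ± 0.446 and 4.49% ± 0.331, and exon 2 of Syt1, a calcium sensor of synaptic vesicles, 3.18% ± 0.710. Exons are numbered along the chosen annotated transcript, whose choice by matched boundaries favours transcripts with extra exons. These exons, called low inclusion exons, were defined by depth alone. Reads across splice junctions were not counted, so skipping of the exons was not measured.

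Outside measured genes, 1256 regions of 500 bp or more had a unique depth of at least 20 in every lane, 1.26 megabases in all. The deepest was at chromosome 19, 5797767 to 5802671, with a mean depth of 2591. It was followed by chromosome 14, 65208918 to 65212791 (1238), chromosome 11, 62365642 to 62366711 (1228), chromosome 19, 5795878 to 5797758 (1152), and chromosome 17, 39983506 to 39985269 (743). No gene model was placed there, so these regions have no name here.

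Genes of both sexes were present in every lane, in a pool that the labels describe as mixed. Xist, the RNA that silences an X chromosome in females, had a level of 76.0 ± 10.3, and the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty had 13.4 ± 2.38, 4.68 ± 1.55, 2.16 ± 0.739 and 1.39 ± 0.467. The list did not differ from random lists (gene permutation test, adjusted p = 0.462). All 5 genes were called higher in lane 4 by the lane test (5 adjusted over the list alone), Xist with 68.7 in lanes 1 to 3 and 83.3 in lane 4 and Ddx3y with 3.58 and 5.78.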

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

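All tests that weigh explanations here were chosen after the results were seen. Of 176 values measured in the 4 lanes, 64 had a lane beyond the two-sided limit of Dixon's test, which chance alone passes in about 1 in 20 groups, and in 61 of the 64 that lane was lane 4. Because lanes 1 to 3 counted as 1 sample, these are largely a single library standing apart, and the values are not independent. Differences below are the lane that stood apart minus the mean of the others.

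In lane 4 the non-unique share was higher by 3.14 percentage points and intron depth by 0.801 percentage points of exon depth, while the share of the top 25 genes differed by -1.83 points and the share on measured exons by -4.43 points. The median log2 level differed by -0.46 for the rod list, -0.23 for Müller glia, -1.56 for lens, -0.13 for the ribbon synapse, -0.30 for glycolysis, -0.39 for genes with processed pseudogenes and 0.56 for the sex chromosome list. These are differences between list medians, and the median of the ratios gene by gene was -0.06 for Müller glia (gene permutation test, adjusted p = 0.487; 0.10 with the trend described below removed), -0.28 for rods and 0.40 for the sex chromosome list. The log2 ratio differed by -0.28 for Gnat1/Gnat2, -0.27 for Pde6a/Pde6c, -0.32 for Pde6b/Pde6c and -0.24 for Gnb1/Gnb3. Exon 3 of Rtn4 was higher by 2.67 points of the median internal exon.

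Of 115 named genes, 48 were picked out by their log2 level, 45 of them for lane 4. Among genes of the photoreceptors that stood apart there were Gnat1 at -0.58, Gnb1 -0.40, Pdc -0.36, Sag -0.44, Prph2 -0.28, Pde6g -0.30, Pde6b -0.28, Pde6a -0.23, Guca1b -0.73, Guca1a -0.39, Rbp3 -0.31, Rom1 -0.21, Unc119 -0.47, Tulp1 -0.30, Nrl -0.46, Esrrb -0.27, Cnga1 -0.13, Cngb1 -0.11, Abca4 -0.18 and Rdh12 -0.17. Not all photoreceptor genes were lower, as Rp1 (0.47), Rpgrip1 (0.13) and Gucy2f (0.30) were called higher in lane 4 by the lane test. Cone genes were at -0.39 for Opn1mw, -0.29 for Gnat2, -0.24 for Pde6h and -0.16 for Gnb3. Genes of metabolism, synapse and translation were at -0.43 for Aldoa, -0.31 for Pkm, -0.46 for Ldha, -0.31 for Hk1, -0.22 for Eef1a1, -0.34 for Slc17a7 and -0.23 for Syp. Markers of other retinal cells were at -0.17 for Dkk3, -0.25 for Apoe, -0.13 for Calb2, -0.16 for Pax6 and -0.11 for Ndrg1. Of the genes lower in lane 4 so far, the lane test called none of Cnga1, Cngb1, Rdh12, Gnb3, Pde6h, Dkk3, Calb2, Pax6 and Ndrg1. The crystallins were at -3.36 for Cryaa, -2.39 for Crybb2 and -2.01 for Cryba1. Higher in lane 4 were Xist by 0.27, Ddx3y by 0.56, Rgs5 by 0.31, Cabp5 by 0.13, Syt1 by 0.11 and Atp1b2 by 0.0522. With the trend with GC content, length and level described below removed, several of the genes lower in lane 4 were near 0 or turned higher, which for some rests on level being part of the trend. Pde6g was then at 0.19, Rom1 at 0.18, Guca1a at 0.0761, Tulp1 at 0.0571, Rdh12 at 0.0547, Syp at 0.0545, Slc17a7 at 0.0321, Pkm at 0.0199, Eef1a1 at 0.0137, Aldoa at -0.00238, Apoe at 0.0988, Calb2 at 0.15 and Ndrg1 at 0.0476. With level left out of the trend, Aldoa stayed at -0.23, Pkm at -0.14, Slc17a7 at -0.14, Eef1a1 at -0.12, Guca1a at -0.14, Tulp1 at -0.11, Syp at -0.0729, Pde6g at -0.0536, Apoe at -0.0333, Rdh12 at -0.0327 and Rom1 at -0.00458, and only Calb2 (0.0575) and Ndrg1 (0.0111) of these were above 0. In other lanes, Gngt2 stood apart in lane 1 by 0.0658, Rps27 in lane 2 by -0.30 and Bfsp1 in lane 3 by 0.0284.

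Of 20 lists, those of lens, sex chromosome, pseudogene, glycolysis and cilium genes passed the comparison of lane 4 with lanes 1 to 3. The pseudogene and glycolysis lists share genes called lower in lane 4, among them Aldoa, Pkm and Ldha, so these results are not independent. Rp1, Rpgrip1 and Rpgr are in both the cilium list and the list shared by rods and cones. The rod list, at -0.28, did not pass (gene permutation test, adjusted p = 0.0653), and neither did the shared list (0.506) or the cone list (0.203). The pseudogene list had a median of -0.31 (gene permutation test, adjusted p = 0.00533), but its adjusted p in that gene permutation test was 0.0867 with median depth, 0.582 with the trend removed (median -0.0236) and 0.0657 with level left out of the trend (median -0.14). The cilium list had a median of 0.0166 (gene permutation test, adjusted p = 0.0344). The adjusted p of that gene permutation test was 0.064 with median depth (median 0.0621) and 0.137 with the trend removed (median 0.0673). With non-unique coverage added the cilium median was -0.0534, against -0.12 for all genes. The cilium list still passed in that setting (gene permutation test, adjusted p = 0.0472).

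The lens list had a median log2 ratio of lane 4 over lanes 1 to 3 of -2.01, against -0.07 for all genes, and lay below level-matched random lists (gene permutation test, adjusted p = 0.002). The log2 ratio fell with GC content (r = -0.388 across genes) and rose with exonic length (r = 0.369), but after a trend with GC content, length and level was removed the lens median was still -1.76, with an SD over genes of 1.30 (gene permutation test, adjusted p = 0.002), which argues against that trend as the whole cause. A candidate explanation is more lens RNA in lanes 1 to 3, but the 10 of 13 lens genes called lower in lane 4 are the pattern itself and do not test it. They include Mip and Lim2 (2.93 and 0.0709), a membrane protein of lens fibres, and the corneal gene Aldh3a1 was lower too. Crygc was called higher in lane 4, against a single lens source as the whole cause, although 17.8% of its coverage was non-unique, and Bfsp1 was alike at 0.690 and 0.675. This explanation stays open, and no biological explanation was tested because the labels put all lanes in the same group.

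The glycolysis list had a median log2 ratio of -0.29 with an SD over genes of 0.11 (gene permutation test, adjusted p = 0.022). After the trend with GC content, length and level was removed it was -0.0667 with an SD of 0.14 (gene permutation test, adjusted p = 0.151), the call ending because the median moved toward 0, but with level left out of the trend it was -0.15 and still passed (adjusted p = 0.0267), so the trend cannot be told apart from a change of these genes. A smaller share of rod RNA in lane 4 is another candidate explanation. The rod list was at -0.08 after removal of the trend and the list shared by rods and cones at 0.0666, neither past the threshold (gene permutation test, adjusted p = 0.137 and 0.204). With level left out they were at -0.15 and -0.000154 (gene permutation test, adjusted p = 0.060 and 0.569), again without a call, which keeps that open.

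Xist and all 4 Y-linked genes were called higher in lane 4, Xist by a log2 ratio of 0.27. A different ratio of the sexes would move Xist and Y-linked genes apart, and the uncorrected values argue against it. After the trend was removed, however, Xist was at -0.02, or at 0.0719 with level left out of the trend, while the Y-linked genes had a median of 0.38 with the full trend. The sign of Xist thus depends on the trend used, so a different ratio of the sexes cannot be told apart, and the trend does not account for the Y-linked genes. The labels do not give the sexes in each lane, so this biological explanation was not tested further.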

How the results depend on the processing

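Alternatives for lane 4 against lanes 1 to 3, for levels of named genes, for the dispersion of lanes 1 to 3, for leaving out genes with shared bases and for counting each lane as a sample were chosen after the data were examined, and the cause of changes was not tested unless a setting's construction gives it. Of 218 alternatives for gene list levels 215 kept direction and side of the threshold, as did all 9 for the rod to cone pairs (4.17 to 4.27 with a lane left out). The ganglion cell list, 1.35 above all genes, was 1.10 with median depth and 0.12 with genes placed by 8 or more boundaries and then did not pass. The lens list, at -0.16, was at -0.17 to 0.57 with a lane left out and turned positive without lane 4.

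Genes that differ between lanes numbered 1220. They numbered 3066 with the dispersion of lanes 1 to 3 (chosen after the data were examined; 1894 above and 1172 below the expected share of lane 4), 5178 without division by dispersion, and 0 to 1018 with a lane left out, 0 without lane 4. Lane agreement was 0.991 with median depth. Wider or stricter limits moved counts by construction. The share of the top genes was 9.06% for 10 genes and 21.4% for 100, genes dominated by non-unique coverage were 329 at 25% and 57 at 75%, low inclusion exons 232 under 10% and 274 at depth 50, and regions 390 at depth 50 and 379 at 1000 bp. Intron depth was 2.77% at exonic depth 50 and 0.187% with the median over intron bases. Evenness was 1.01 with longer end parts and 1.07 at 3000 bp.

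With non-unique coverage added, Xist was at 49.1, Eif2s3y at 8.56, Ddx3y at 2.98 and Uty at 0.887, mainly because the total then includes non-unique bases. The non-unique shares of these genes themselves were 1.07%, 0%, 0% and 0.174%. A pseudocount does not enter the levels of the sex chromosome genes, so that alternative was not run for them. Of the alternatives for levels of single named genes, 212 moved the level by at least 1 SD and 558 by less.

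For lane 4 against lanes 1 to 3, lens and sex chromosome lists kept their calls in every setting run. With non-unique coverage added, with a median over all genes of -0.12 in place of -0.07, medians turned to -0.0406 for amacrine cells, -0.0362 for blood vessels and -0.0534 for cilium. The cilium list still passed there (gene permutation test, adjusted p = 0.0472). With median depth they were 0.0684 for ganglion cells and 0.0405 for oligodendrocytes, while cilium (0.0621) and genes with pseudogenes (-0.25) no longer passed. Oligodendrocytes ranged from -0.0543 to 0.0225 with a lane left out. Centred on all genes, cones were at 0.0530, bipolar cells 0.0625, Müller glia 0.0123, horizontal cells 0.0447, ganglion cells 0.0146, microglia 0.0327 and oligodendrocytes 0.0537. With the trend removed, cones were at 0.0400, rods and cones 0.0666, bipolar cells 0.0626, Müller glia 0.10, horizontal cells 0.0476, ganglion cells 0.11, microglia 0.0574, oligodendrocytes 0.12, the ribbon synapse 0.0321 and the visual cycle 0.0351, and cilium (0.0673), glycolysis (-0.0667) and genes with pseudogenes (-0.0236) no longer passed. Apart from cilium, no list that turned had passed before. No paired analysis between groups was possible because all lanes belong to the same group. Unique against non-unique bases and the gene pairs were compared within lanes. Depth limits weakly covered genes, which were mostly not placed.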

Other observations

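Ribosomal protein genes, a list chosen after the data were examined, had a median non-unique share of 44.0% over 62 measured genes, and 27 of them were among the 154 genes dominated by non-unique coverage. Their median lay above random lists in a gene permutation test with p = 0.0002, the smallest that 10000 lists can give.

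Low inclusion exons, which were defined by depth alone, had lengths that were multiples of 3 more often than other internal exons. The share was 52.4% of 479 exons, against 39.3% over all eligible exons, these 479 included, with a two-sided Fisher's exact p of 6.5e-09. This test was chosen after the data were examined, and exons of a gene are not independent.

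Outside the fixed lists, several genes chosen after their values were seen differed strongly between lanes. Cryab, a small heat shock crystallin, had a level of 135 in lanes 1 to 3 and 27.5 in lane 4, Igfbp7, a secreted growth factor binding protein, 22.2 and 7.51, and the basement membrane genes Col4a1 and Nid1 had 7.90 and 3.69 and 2.60 and 0.444. Higher in lane 4 were Lrp8, a reelin receptor, with 11.7 and 18.4, and the chromatin gene Atrx, with 17.9 and 24.5. This choice does not follow the ranking by log2 ratio, so it shows no common theme. Eps8l1, with 8.89 and 0.762, was lower by more than Cryab, and Rps7, with 21.9 and 9.89, by more than Col4a1. Col24a1, with 1.07 and 2.49, and 6430590A07Rik, with 3.88 and 7.55, were higher by more than Lrp8.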
